A study of Pimephales promelas with 139 samples.

How the data were processed

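The measurements are mRNA-seq counts of whole fathead minnow larvae from control water and 5 concentrations of ethinyl estradiol in 3 experiments. Per the labels' protocols, single whole larvae were frozen with a steel bead and lysed, and libraries were made from 250 ng of RNA with the SENSE mRNA-Seq V2 kit. The authors deposited 1 table of raw read counts, whole numbers per transcript and library, and per the series' design text the reads were mapped to known transcripts of the species. Per the submitters' processing notes bcl2fastq 2.19.1, limma 3.40.6 and edgeR 3.26.8 were used; the aligner, the counter and whether the counting used strand are not given in the sources used here, and neither is how reads shared by similar transcripts were assigned. The table holds 37085 identified transcripts, with identifier numbers up to 47577, and its least abundant row has 117 counts over all libraries, so some filtering came before; its rule is not given in the sources used here. A further row without an identifier holds 0 to 13 reads per library, 1.6e-05% of all reads, and was left out. No column of per-sample values was left unmapped (0 columns).

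Concentration and experiment come from the labels, and library names in the table match the sample titles. None of the identifiers matched the reference gene table given for the organism (0 of 64593 genes), so the 23 gene lists fixed in advance, with 743 symbols, were not tested, and rows were not summed per gene. No 2 libraries of a group were copies: over 503 pairs of libraries of the same group and experiment, the chi-square statistic of their counts over 29017 transcripts was 9.44 to 323 times its degrees of freedom.

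Counts were analysed in R 4.3.3 with edgeR 4.0.16. Transcripts were kept by filterByExpr with the 6 groups (minimum count 10, minimum total 15), which left 35340, and libraries were scaled by TMM. One quasi-likelihood model (robust) with group and experiment was fitted to all libraries, so all comparisons share 1 estimate of the spread. Each concentration was tested against control and against the concentration below it. A joint F-test compared all groups, and a trend was fitted on log2 of the concentration plus 0.12 ng/L. The interaction of 10 ng/L with experiment was fitted on control and 10 ng/L larvae (32589 transcripts) and the differences between experiments on the controls (33388 transcripts). Calls are Benjamini-Hochberg adjusted p-values under 0.05 by edgeR. SEs of log2 changes are the change divided by the square root of its F statistic. CPM are counts scaled by edgeR to the TMM-adjusted library total, and slopes per doubling were fitted to log2(CPM + 0.1).

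The naming rule, fixed before the data were examined for tables without gene names, takes per comparison the 2 called transcripts with the largest rise and the 2 with the largest fall among those with a mean of at least 1 CPM and the same direction in all 3 experiments; others are marked where they appear. For the classifier, log2 CPM (prior count 2) were standardised within each experiment, the 500 transcripts with the smallest edgeR p between control and 10 ng/L in 2 experiments were chosen, a ridge logistic model was fitted by glmnet 4.1.10 (penalty by 5-fold cross-validation), and the third experiment was scored. Its AUC was tested by 1e+05 permutations of the labels within experiments, one-sided. Shared controls were simulated 50 times with normal noise of each transcript's own residual spread.

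The model was tested on simulated data before use: negative binomial counts with the real means, depths and dispersions, 50 transcripts at each of 4 fold sizes out of 35340. The counts were drawn independently around 1 mean per transcript, without experiment differences or outlying libraries. The shares of false calls below therefore need not hold for the real data. At the group sizes of 10 ng/L against control it recovered 24% of 1.25-fold, 62% of 1.5-fold, 82% of 2-fold and 100% of 4-fold changes with 7 false calls among 141; at those of 0.12 ng/L it recovered 28, 48, 90 and 98%, with 11 false calls among 143. A total of 8756290 or more counts per library and a median of 117 counts per transcript and library set the precision; transcripts near 0.1 CPM rest on 2 or 3 reads in a control larva.

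Alternatives listed before the data were examined were RLE scaling, 2 other low-count filters, DESeq2 1.42.0, limma-voom 3.58.1, no experiment term, the title number as a block, a correlation within runs of 5 title numbers, only the 2 groups compared, each experiment left out, libraries under 0.5 times the median total left out, an adjusted p under 0.01, at least 2-fold changes, other dose scales, other classifier sizes and halved controls. Leaving out single libraries at 2.5 ng/L and classifiers with 1 transcript or without the 4 transcripts called at 1.2 ng/L were added after the data were seen.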

Results

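Fathead minnow (Pimephales promelas) larvae, the young of a small freshwater fish widely used in toxicity testing, were held for 48 h in static water with ethinyl estradiol, the synthetic estrogen of oral contraceptives. The exposure began 48 h after hatching and the larvae were collected at 96 h. Messenger RNA of whole larvae was sequenced and counted per transcript. The series holds 29 libraries from control larvae, 17 at 0.12 ng/L, 30 at 1.2 ng/L, 18 at 2.5 ng/L, 17 at 5 ng/L and 28 at 10 ng/L. They come from 3 experiments of 46, 46 and 47 libraries, and every experiment holds every concentration. Total counts ran from 8756290 to 32906788 per library with a median of 23453744, and the group medians lay between 22.1 and 24.1 M counts. The deposited table lists transcripts by identifier only and does not pair them with gene names, so transcripts are named here as the file gives them. The labels do not say which larvae shared a vessel or parents, so the p-values measure only the spread between these libraries. Vitellogenin, the egg yolk precursor that estrogens are known to raise in fish liver, was not looked up for the same want of names.

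The stated aim of the series was to find expression markers of estrogen exposure in larvae, which makes the lowest concentration with a measurable response the first question. At 1.2 ng/L, 4 transcripts rose and none fell. FMt030408 went from 0.469 ± 0.213 CPM (SD, n = 29) in controls to 12.1 ± 7.94 CPM (SD, n = 30), and FMt030407 from 0.105 ± 0.0938 to 2.28 ± 1.54 CPM. The other 2, FMt030406 and FMt019919, lie outside the naming rule and are given because the list is short; FMt019919 went from 0.359 ± 0.191 to 0.766 ± 0.29 CPM. FMt030406, FMt030407 and FMt030408 have consecutive identifiers, and reads shared between near-identical transcripts cannot be excluded for them. Of the 30 larvae at 1.2 ng/L, 28 lay above the highest control for FMt030408, 27 for FMt030407, 26 for FMt030406 and 11 for FMt019919. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 35340 transcripts, the log2 changes were 4.69 ± 0.25 (SE; adjusted p = 1.77e-35) for FMt030408, 4.34 ± 0.31 for FMt030407, 3.76 ± 0.33 for FMt030406 and 1.07 ± 0.15 (adjusted p = 7.26e-07) for FMt019919. Each rise had the same direction in all 3 experiments. Without experiment 1 the rise of FMt019919 was 0.89 on the log2 scale and missed the threshold, with an adjusted p of 0.0765.

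The same 4 transcripts were called at 2.5, 5 and 10 ng/L, at levels that climbed with the concentration. FMt030408 averaged 31.5 ± 15.8 CPM (SD, n = 18) at 2.5 ng/L, 94.2 ± 58.6 CPM (n = 17) at 5 ng/L and 173 ± 61.7 CPM (n = 28) at 10 ng/L, which is 65.5-, 200- and 368-fold the control level in the fit. FMt030407 was 320-fold and FMt030406 236-fold the control level at 10 ng/L. FMt019919 stayed far lower, at 1.23 ± 0.373, 2.16 ± 0.658 and 3.39 ± 1.08 CPM, and reached 9.16-fold. From 2.5 ng/L upward every larva exceeded every control for FMt030408, FMt030407 and FMt030406; for FMt019919 this held for 17 of 18 larvae at 2.5 ng/L and for all 17 and 28 larvae at 5 and 10 ng/L. Over the 93 larvae at 1.2 to 10 ng/L, log2 CPM rose by 1.36 ± 0.08 (SE) per doubling of the concentration for FMt030408, 1.4 ± 0.08 for FMt030407, 1.43 ± 0.08 for FMt030406 and 0.67 ± 0.03 for FMt019919. Within experiments 1, 2 and 3 the slope of FMt030408 was 1.35 ± 0.13, 1.44 ± 0.14 and 1.29 ± 0.12, and that of FMt019919 was 0.64 ± 0.05, 0.72 ± 0.06 and 0.64 ± 0.07.

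**Figure D1:**
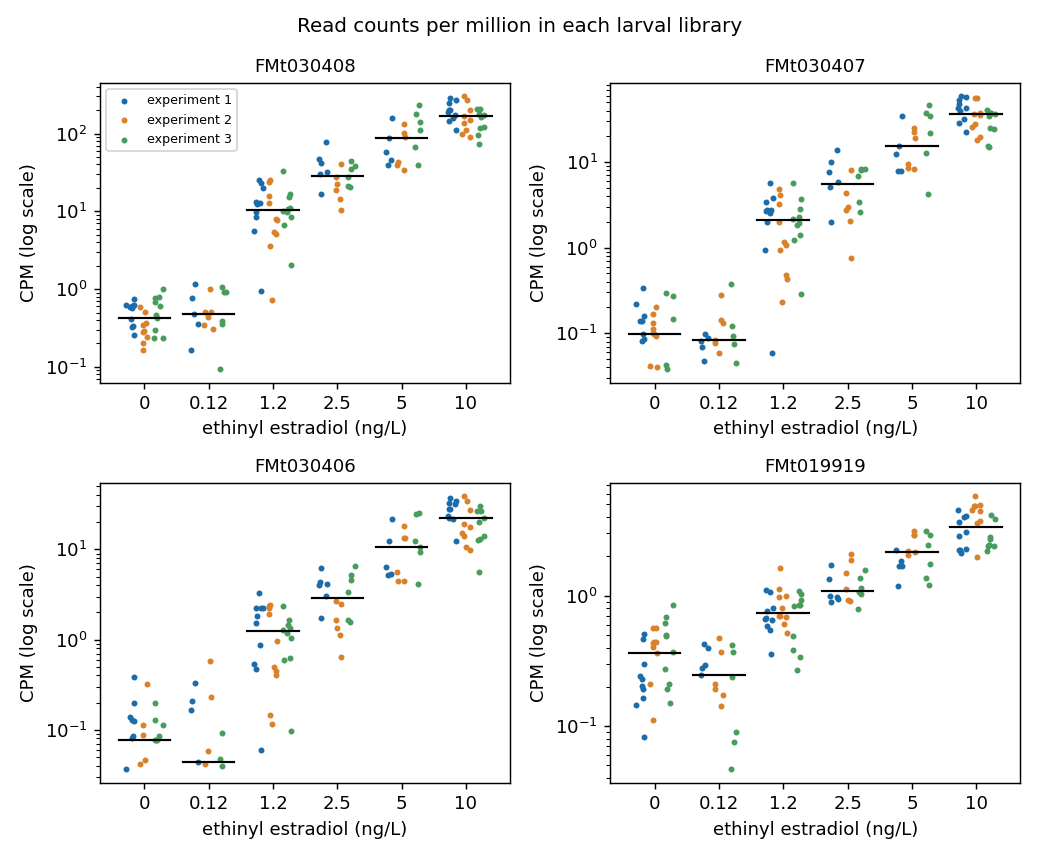
CPM (counts scaled to the library total) (log scale, larvae with no read for a transcript not drawn) of FMt030408, FMt030407, FMt030406 and FMt019919 in each library by ethinyl estradiol concentration in ng/L, with 0 for controls; points are coloured by experiment and black lines are group medians. FMt030408 has a median of 0.42 CPM in controls, 0.475 CPM at 0.12 ng/L, 10.3 CPM at 1.2 ng/L and 169 CPM at 10 ng/L.

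At 0.12 ng/L no transcript passed the threshold in edgeR, and 1442 of 35340 had an unadjusted p under 0.05, where chance alone gives 1767. DESeq2 and limma-voom also called 0 transcripts. FMt030408 had 0.572 ± 0.327 CPM (SD, n = 17) there, with 3 of 17 larvae above the highest control. Its log2 difference of 0.31 ± 0.33 (SE) is smaller than its own SE (unadjusted edgeR p = 0.347), with the same direction in all 3 experiments. FMt019919 had 0.261 ± 0.132 CPM. Fitting only the 0.12 ng/L and control larvae gave 8 calls, dropping the experiment term 2, and leaving out the low-count filter 1.

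Neighbouring concentrations were also set against each other. Between 0.12 and 1.2 ng/L the 4 transcripts rose again, by 4.38 ± 0.30 (SE, log2) for FMt030408 and 1.52 ± 0.19 for FMt019919. FMt043101, named because the list is short, was called lower at 1.2 ng/L by 2.99 on the log2 scale, but its group median was 0.46 CPM at 0.12 ng/L and 0.316 CPM at 1.2 ng/L, and 1 larva at 0.12 ng/L held 84.8 CPM; its direction was not shared by all 3 experiments. From 2.5 to 5 ng/L only 3 transcripts were called, FMt030406, FMt030407 and FMt030408, by 1.97 ± 0.29, 1.81 ± 0.27 and 1.61 ± 0.25 (SE, log2). From 5 to 10 ng/L the single call was FMt036339, by 2.25 ± 0.30 (edgeR adjusted p = 3.06e-07); with the title number as a block it became 1.47 and was not called. From 1.2 to 2.5 ng/L 208 transcripts were called, 203 of them higher, which included FMt030408 at 1.35 ± 0.21 and FMt046529 at 1.35 ± 0.35, with FMt046088 and FMt016846 lower by 2.5 and 0.86. FMt046088 had group medians of 0.547 CPM at 1.2 ng/L and 0.409 CPM at 2.5 ng/L, and 3 of 30 larvae at 1.2 ng/L lay above the highest control, up to 28.7 CPM. Without 1 library, replicate 7 of the 2.5 ng/L group, 4 transcripts were called. FMt046088 was still called then, at -2.46 (edgeR adjusted p = 0.0434), while FMt016846 at -0.81 and FMt046529 at 0.89 were not (adjusted p = 0.723 and 0.852). Over the 4 alternative settings of this comparison FMt046088 kept its call in 2, at log2 changes from -2.49 to -1.09.

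The count at 2.5 ng/L against control was the highest of any concentration, with 951 transcripts called, 894 higher and 57 lower. Their median absolute log2 change was 0.46, and 25 changed at least 2-fold. Among those named by the fixed rule, FMt044460 was lower by 3.22 ± 0.90 (SE, log2) and FMt019848 by 1.02 ± 0.28. FMt044460 has control values from 0 to 26.6 CPM around a median of 0.226 CPM, against 0 to 0.564 CPM at 2.5 ng/L. The count rests on that same library, replicate 7 from experiment 1: with it left out, 5 transcripts were called. All 951 kept their sign without it, and their median absolute log2 change was 0.2. FMt044460 and FMt019848 were no longer called, at nearly the same log2 changes of -3.21 and -0.97 (adjusted p = 0.352 and 0.391). The 5 called are the 4 transcripts above and FMt045413, named after its value was seen, which was lower by 1.95 on the log2 scale (edgeR adjusted p = 0.0323). In this library 30768 transcripts had a read, against 34800 in the next lowest and 36597 in the median library, and its scaling factor was 0.468, against 0.785 for the next lowest. limma-voom called 4 transcripts at 2.5 ng/L with all libraries. Of the 951, 4 were also called at 5 ng/L, where only 5 transcripts were called in all. The median log2 change of the 951, with sign, was 0.45 at 2.5 ng/L, 0.16 at 5 ng/L and 0.07 at 10 ng/L.

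At 5 ng/L, 5 transcripts were called: the 4 that rose at 1.2 ng/L, and FMt002788, which fell by 0.37 ± 0.08 (SE, log2). FMt002788 averaged 108 ± 31.9 CPM (SD, n = 29) in controls, 85.5 ± 22.6 CPM (n = 17) at 5 ng/L and 81.8 ± 24.2 CPM (n = 28) at 10 ng/L, where it was called again with a fall of 0.39 ± 0.07 on the log2 scale. The call at 5 ng/L, with an adjusted p of 0.0428, was lost without any one of the experiments, without the experiment term, without the low-count filter and in a fit of the control and 5 ng/L larvae alone. The call at 10 ng/L was lost without the experiment term.

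At 10 ng/L, 56 transcripts were called, 34 higher and 22 lower, and 55 of them kept their direction in all 3 experiments. Most changes were small: 36 were below 1.5-fold, 10 reached 2-fold, and the falls had a median of -17.8%. Below the 4 transcripts already named, FMt036339, chosen after its values were seen, rose by 2.52 ± 0.25 (SE, log2; edgeR adjusted p = 3.54e-14). It went from 1.96 ± 0.488 CPM (SD, n = 29) in controls to 12.1 ± 19.7 CPM (SD, n = 28), and 18 of 28 larvae exceeded the highest control, with a top value of 79.2 CPM. The experiments were unequal: the mean went from 2.2 to 2.8 CPM in experiment 1, from 1.95 to 20.1 CPM in experiment 2 and from 1.73 to 14.4 CPM in experiment 3. Over the alternatives the log2 change ran from 1.7 with limma-voom to 3.18 without experiment 1, called each time. FMt043678 and FMt043681, also chosen after the fact, rose by 1.08 ± 0.17 and 2.05 ± 0.36, the latter from 0.195 ± 0.166 CPM. FMt043681 was not called without experiment 3 or with limma-voom, with or without a correlation within runs of title numbers (log2 change down to 1.27, adjusted p up to 0.308). Among the falls named by the rule, FMt003762 went from 1.88 ± 1.17 to 0.543 ± 0.519 CPM, lower by 1.77 ± 0.34 (log2), and FMt042784 from 22.9 ± 9.85 to 14.8 ± 8.61 CPM, lower by 0.68 ± 0.16. FMt003762 was not called without experiment 1 or without experiment 2, and FMt042784 was lost without either of these, with limma-voom, without the experiment term and without the shallow libraries. With the 9 libraries under 0.5 times the median total left out, 34 transcripts were called, and with any one experiment left out between 18 and 34.

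**Figure D2:**
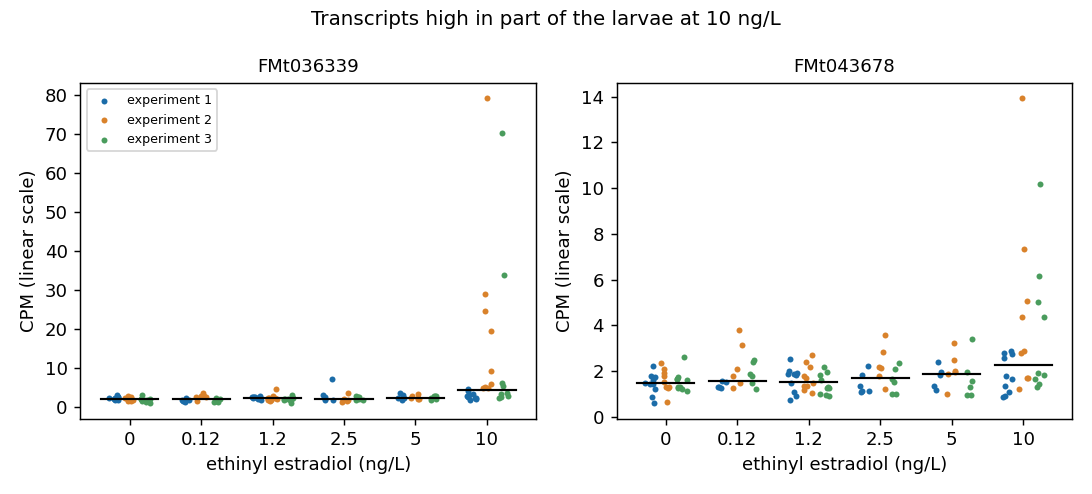
CPM (counts scaled to the library total) (linear scale) of FMt036339 and FMt043678 in each library by ethinyl estradiol concentration in ng/L, with 0 for controls; points are coloured by experiment and black lines are group medians. For FMt036339, 18 of 28 larvae at 10 ng/L lie above the highest control of 3.08 CPM, up to 79.2 CPM.

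Smaller shifts were also called at 10 ng/L; those in this paragraph were chosen after their values were seen. FMt041475 went from 164 ± 44.1 CPM (SD, n = 29) in controls to 118 ± 33.5 CPM (n = 28), a fall of 0.48 ± 0.07 (SE, log2), with 132 ± 28.6 CPM at 5 ng/L. FMt008590 went from 5.32 ± 1.06 to 7.73 ± 1.76 CPM, a rise of 0.54 ± 0.09, and 13 of 28 larvae exceeded the highest control. The neighbours FMt007494, FMt007495, FMt007496 and FMt007497 rose by 0.81, 0.77, 0.86 and 0.78 on the log2 scale. FMt007497 went from 100 ± 40.8 to 175 ± 73 CPM. Lower concentrations showed smaller rises, without a call at 0.12 ng/L (0.41, 0.38, 0.46 and 0.36) or 5 ng/L (0.49, 0.5, 0.53 and 0.47). At 2.5 ng/L they were 0.6, 0.64, 0.65 and 0.43, and all but FMt007497 were called. Those calls held in 4, 6 and 6 of 14 alternative settings. From 5 to 10 ng/L the differences of 0.32, 0.27, 0.33 and 0.32 were not called. Whether controls differ from all exposed larvae was not tested here. Of these 4 neighbours, none was called at 10 ng/L without experiment 1 or without experiment 2. FMt007495 kept its call there in 10 of 14 alternative settings, at log2 changes down to 0.59, and each of the others in 12 of 14.

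Over all concentrations, 114 transcripts differed between the 6 groups in the joint test, 37 without replicate 7 of the 2.5 ng/L group. The trend test, against log2 of the concentration plus 0.12 ng/L, called 54 transcripts, 32 rising and 22 falling, and 39 of the 56 called at 10 ng/L were among them. The slope was 1.41 ± 0.04 (SE, log2 per unit) for FMt030408, 0.33 ± 0.04 for FMt036339, 0.09 ± 0.01 for FMt008590 and -0.06 ± 0.01 for FMt041475. The effect of 10 ng/L was then compared between experiments: by the interaction test in edgeR 0 of 32589 transcripts differed, limma-voom also gave 0, and 1275 had an unadjusted p under 0.05. FMt036339 had the unadjusted p of 0.000106 and the adjusted p of 0.742 in that test. Among the 29 controls alone, 21 transcripts differed between experiments, led by FMt003945 and FMt002788, named for their small p after the values were seen. FMt003945 was lower in experiments 2 and 3 than in experiment 1 by 2.41 and 2.03 on the log2 scale, and FMt002788 was higher there by 0.62 and 0.86.

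Overlaps between concentrations were read against what shared controls give by themselves. The 4 transcripts were shared by the calls at 1.2, 2.5, 5 and 10 ng/L in every pair, and 4 were shared in each of these pairs when the controls were halved so that no pair had a control in common. Independent lists would share 0.1 transcripts at 1.2 and 2.5 ng/L and 0.0038 at 5 and 10 ng/L. The simulated unchanged groups shared 0, but adjusted calls are rare in such groups, so this is no reference for lists of the real lengths. The calls at 2.5 and 10 ng/L shared 18 transcripts with all controls, where independent lists give 0.86 higher and 0.035 lower ones, but 4 without replicate 7 of the 2.5 ng/L group. With halved controls 4 were shared too, from lists that were themselves shorter, 18 calls in place of 951 at 2.5 ng/L (first set of 15 controls) and 40 in place of 56 at 10 ng/L (the other 14 controls). Of the 56 transcripts called at 10 ng/L, 56 had the same sign at 1.2 ng/L, 56 at 2.5 ng/L, 55 at 5 ng/L and 49 at 0.12 ng/L. Unchanged groups simulated against the same controls gave 97.4, 94.5, 94.5 and 93.6% same sign. Those are the 56 smallest p-values of pure noise, while the real 56 include large changes. The shares with all controls therefore decide nothing on a shared response. With halved controls unrelated signs would give 50%. With the 15 controls under 10 ng/L, which gave 17 calls, the share was 58.8% at 0.12 ng/L (10 of 17), 82.4% at 1.2 ng/L and 88.2% at both 2.5 and 5 ng/L. With the 14 controls under 10 ng/L, which gave 40 calls, it was 72.5% at 0.12 ng/L (29 of 40), 87.5% at 1.2 ng/L, 82.5% at 2.5 ng/L and 90% at 5 ng/L; these shares were not tested. The covariance of log2 differences between 5 and 10 ng/L was 0.0188 against 0.0119 in the simulation, and that of 0.12 ng/L was 0.0121 with 1.2 ng/L, 0.0185 with 2.5 ng/L, 0.0149 with 5 ng/L and 0.0153 with 10 ng/L, against 0.0119 to 0.012. Without replicate 7 the covariance of 0.12 and 2.5 ng/L was 0.0161 against 0.0112. These differences from the simulation were not tested.

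To ask whether a marker set learnt in some larvae identifies exposure in others, 500 transcripts and a ridge model were fitted to control and 10 ng/L larvae of 2 experiments and applied to the third. The mean AUC (the chance that an exposed larva scores above a control, 0.5 for no separation) was 0.902 at 10 ng/L, 0.818 at 5 ng/L, 0.791 at 2.5 ng/L, 0.76 at 1.2 ng/L and 0.718 at 0.12 ng/L. The permutation p-values within experiments, one-sided and adjusted over the 5 concentrations, ran from 5e-05 to 0.0079. In experiments 1, 2 and 3 the AUC at 0.12 ng/L was 0.76, 0.778 and 0.617. With 5000 transcripts its mean there was 0.647 and missed the threshold (adjusted permutation p = 0.054). The 4 transcripts held the first 4 ranks in each of the 3 training sets. The first-ranked transcript alone, a choice made after the data were seen, separated every larva at 1.2 ng/L and above from the controls of its experiment, with an AUC of 1 at each concentration, and gave 0.616 at 0.12 ng/L. Without the 4 transcripts the 500-transcript model gave 0.876 at 10 ng/L and 0.73 at 0.12 ng/L.

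**Figure D3:**
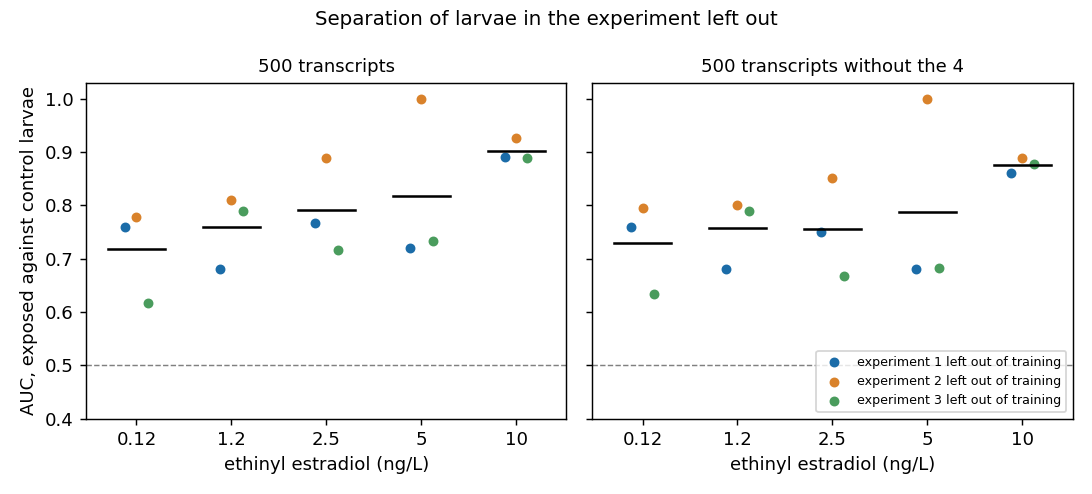
AUC of exposed against control larvae (vertical axis from 0.4, dashed line at 0.5) by ethinyl estradiol concentration in ng/L, for models trained on 10 ng/L and control larvae of the other experiments; points are experiments, black lines their mean. With 500 transcripts the mean runs from 0.718 at 0.12 ng/L to 0.902 at 10 ng/L, and without the 4 transcripts from 0.73 to 0.876.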

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

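Settings that left out a single library, and classifiers with 1 transcript or without the 4 transcripts called at 1.2 ng/L, were chosen after the data were seen; all other settings were fixed before. The 4 calls at 1.2 ng/L ranged from 3 to 6 over the alternatives and kept their upward direction. At 0.12 ng/L the count stayed at 0 except for 1 call without the low-count filter, 2 without the experiment term and 8 in a fit of the 2 groups alone. At 5 ng/L, DESeq2 called 16 transcripts in place of 5.

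The 951 calls at 2.5 ng/L became 1448 with DESeq2, 4 with limma-voom, 4 with limma-voom and a correlation within runs of 5 title numbers, 4 in a fit of the 2 groups alone, 4 without experiment 1, 11 without experiment 3, 164 at an adjusted p under 0.01 and 25 with at least 2-fold changes. With each of the 18 libraries at 2.5 ng/L left out in turn the count ran from 5, without replicate 7, to 1536, without replicate 2; replicates 28, 57, 62 and 63 each lowered it over 1.5 times, to 487, 578, 595 and 625. The 208 calls between 1.2 and 2.5 ng/L became 325 with RLE scaling, 3 with limma-voom and 4 without replicate 7. Leaving out experiment 1 also leaves out replicate 7; for the other settings at these concentrations the cause was not tested.

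The 56 calls at 10 ng/L became 100 with DESeq2, 96 in a fit of the 2 groups alone and 23 without the experiment term. They became 18, 26 and 34 without experiments 1, 2 and 3, and 34 without the 9 shallow libraries. An adjusted p under 0.01 left 34 and at least 2-fold changes left 10, counts that a stricter threshold lowers by construction. For the other settings the cause was not tested. DESeq2 kept 54 of the 56 and limma-voom 40. The single call between 5 and 10 ng/L became 5 with limma-voom, cause not tested. The joint test's 114 became 314 with DESeq2, 15 with limma-voom, 17 and 26 without experiments 1 and 3, 45 without the shallow libraries, 37 without replicate 7 and 25 at an adjusted p under 0.01. The trend's 54 became 22 without the experiment term, 20, 21 and 25 without experiments 1, 2 and 3, 29 on a linear dose scale and 30 at an adjusted p under 0.01. The interaction stayed at 0 and the control differences between 16 and 21.

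The classifier's AUC at 0.12 ng/L was 0.647 with 5000 transcripts and 0.616 with 1, neither past the threshold; at the other concentrations every setting passed. The 18 calls shared by 2.5 and 10 ng/L became 4 with halved controls, where the lists themselves shrank from 951 to 18 and from 56 to 40.

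No pairing of the larvae by the numbers in the sample titles was detected. Deviations of larvae with the same number correlated by -0.013 on average, against -0.0058 for other numbers of the same experiment, and for 20 libraries the best match had its own number. With the title number as a block in place of experiment, the calls at 2.5 ng/L became 4, those from 1.2 to 2.5 ng/L 4, the single call from 5 to 10 ng/L 0 and the joint test 19; the remaining counts stayed within 1.5 times.

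For single named transcripts, 259 of 263 alternative values of FMt030408, FMt030407, FMt030406 and FMt019919 kept direction and call and 4, all of FMt019919, kept the direction only; of 282 values of the other named transcripts, 193 kept both and 89 the direction only. None turned its sign. DESeq2 gave no adjusted p for 4 named values, which are not counted. Depth limits the weak transcripts: FMt030406 had a mean of 2.17 reads per control library, so its fold change rests on few control reads.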

Other observations

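The relations between larvae, the transcripts switched on or off, the neighbouring identifiers and the tests on replicate 7, on the split with the most calls and on the control levels of FMt036339 were chosen only after the results were seen.

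Larvae of 1 concentration differed widely in the strongest responders, and in step. Over the 93 larvae at 1.2 to 10 ng/L, after the mean of each concentration and experiment was taken off, FMt030408 and FMt030407 correlated with Pearson's r = 0.92 (0.91 without the 2 outermost larvae) and Spearman's rho = 0.91, and FMt030408 and FMt030406 with r = 0.90 and rho = 0.89. All these have a permutation p of 1e-05, the smallest that 1e+05 permutations give, and 3e-05 after adjustment over the 6 relations computed. FMt030406 to FMt030408 have consecutive identifiers, and reads shared between near-identical transcripts cannot be excluded as the source of these correlations. FMt019919, which rose with dose in every experiment too, had no detected correlation with FMt030408 among larvae of the same treatment: r = -0.05 (permutation p = 0.66; -0.08 without 2 larvae) and rho = -0.02 (p = 0.88). Among the 56 transcripts called at 10 ng/L, 6 of the steps between successive identifiers in numerical order were at most 2, against a mean of 0.14 and a maximum of 3 in 1000 random draws. These steps include FMt030406 to FMt030408 and FMt007494 to FMt007497. Without gene names it is not known whether such neighbours belong to 1 gene, so the steps may not count separate genes.

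Apart from these comparisons, 64 transcripts were either on or off in a larva: a 90th percentile of at least 3 CPM, at least 10% of libraries below 5% of it, at least 10% above 30% of it and under 10% between. A library above 15% of it counted as on. By Fisher's test with simulated p-values 22 of these differed between the 3 experiments after adjustment (smallest adjusted p = 0.00032), and 0 differed between the 6 concentration groups (smallest adjusted p = 0.63; 2 had an unadjusted p under 0.05). A chi-square test also called 22, and with shuffled experiment labels it called at most 5 in 1000 draws (p = 0.001). FMt046525, FMt031762, FMt039319, FMt041487 and FMt041488 were all on in 35 libraries and all off in the remaining 104, with means of 6.67 and 0.054 CPM. The block was on in 13 of 46 larvae of experiment 1, 5 of 46 of experiment 2 and 17 of 47 of experiment 3. At 2.5 ng/L, 1 larva held 7970 CPM of FMt014388, whose control median was 34.9 CPM; it is replicate 7, the library of unlike composition described next, without which the log2 change fell from 3.23 to 1.06 (edgeR adjusted p = 0.599).

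The first pattern is the 951 calls at 2.5 ng/L, far more than the 5 at 5 ng/L and the 56 at 10 ng/L. Only 5 of the 951 kept the call without replicate 7, while leaving out any other library of the group left at least 487, so a candidate explanation for the count is the unlike composition of this library, in which 2387 transcripts lay over 4-fold above and 8300 over 4-fold below the control mean; the median other library had 290.5 such transcripts. It is not sufficient by itself in other groups: in 17 shuffles of the labels that put it into another set of exposed larvae, that set had a median of 1 call and at most 253. A response of the group stays open: without replicate 7 the log2 changes of the 951 were a median of 0.48 times those with it (quartiles 0.33 and 0.69), all 951 kept their sign and 536 had an unadjusted p under 0.05, but the other larvae took part in choosing these transcripts, which keeps it undecided. Over the 894 transcripts that rose at 2.5 ng/L, replicate 7 averaged 2.33 above the controls (log2). The next highest were replicate 53 at 1.2 ng/L (1.06, scaling factor 0.814) and replicate 8 at 0.12 ng/L (0.91, scaling factor 0.785). Replicate 28 at 2.5 ng/L followed with 0.68. So a shift of these transcripts was not limited to the 2.5 ng/L group, and its cause was not tested. Whether the larva of replicate 7 or its RNA or library was unusual stays open too.

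The second pattern is the rise of FMt036339 in part of the larvae at 10 ng/L, 3 of 10 above the highest control in experiment 1, 9 of 9 in experiment 2 and 6 of 9 in experiment 3. Shallow libraries are argued against, as the adjusted p without them was 3.73e-15 (3.92e-24 to 0.000248 over the alternatives), and so is a level that differs between experiments without exposure, since the controls of experiments 2 and 3 averaged 0.839 times those of experiment 1, with an upper bootstrap bound of 0.979. A stronger estrogen response of those larvae, as read by FMt030408, stays open: rho was -0.14 over 28 larvae (permutation p = 0.49; r = -0.2, p = 0.36, and -0.11 without 2 larvae), with an upper 95% bound of 0.27. FMt036339 varied among these larvae with FMt043678 (rho = 0.45, r = 0.48) and with FMt043681 (rho = 0.42, r = 0.46), each with an adjusted p of 0.046 for rho and 0.039 for r, and r = 0.42 and 0.41 without 2 larvae. FMt043678 and FMt043681 have close identifiers, so shared reads or a common gene cannot be excluded for them. Their correlations with FMt036339 may then be 1 relation. A hypothesis is that these 3 transcripts belong to 1 response that only some larvae had begun at 96 h, and no test here separates it from differences in age or vessel.

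The third pattern is that larvae at 0.12 ng/L, where no single transcript was called, scored above controls on transcripts learnt at 10 ng/L in the other experiments. With the 4 transcripts left out and a plain difference of mean standardised values, the AUC was 0.731 at 0.12 ng/L and 0.744 at 1.2 ng/L. It was 0.751 at 2.5 ng/L, 0.777 at 5 ng/L and 0.867 at 10 ng/L. Control and 0.12 ng/L labels were then shuffled 100 times and the transcripts learnt again. As high an AUC was reached by 2 splits, the real one included, the highest other also being 0.731 and their median 0.513. So few shuffles reached this score. It was computed on the larvae and labels in which the pattern was first seen, so the shuffles are no independent test of the pattern. They also treat larvae as exchangeable, although it is not known which shared a vessel. Whether chance explains the pattern is therefore not decided. The model with 5000 transcripts gave 0.647 (adjusted permutation p = 0.054). After linear regression on the log total and log scaling factor the AUC was lower, 0.656 (one-sided permutation p = 0.043, without learning the transcripts again). This p is only just under the 0.05 set beforehand. Whether depth and the scaling factor are the whole cause is therefore not decided. Differences in composition that 1 scaling factor does not capture were not tested and stay open. The score rose little over the 82 larvae from 0.12 to 5 ng/L (rho = 0.12, one-sided permutation p = 0.14, bootstrap interval -0.09 to 0.32; r = 0.1, p = 0.19, and 0.09 without 2 larvae), so a response that grows with dose and a handling difference between controls and all exposed larvae cannot be told apart. A weak response already at 0.12 ng/L may be present, as a hypothesis that needs controls handled in parallel vessels.

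Group labels shuffled within experiments gave 21 splits with the real one. With all libraries no shuffled split reached the counts at 2.5 ng/L (951, highest other split 394), at 10 ng/L (56 and 1), from 1.2 to 2.5 ng/L (208 and 26) and for the trend (54 and 12). Each was reached by 1 of 21 splits, the real one, the smallest share these shuffles can give, not adjusted over the counts. At 2.5 ng/L and from 1.2 to 2.5 ng/L this does not exclude chance, since shuffles without replicate 7 gave up to 4880 and 3218 calls. Other splits did reach the counts at 1.2 ng/L (4, highest other 152), at 5 ng/L (5 and 18), from 0.12 to 1.2 ng/L (5 and 7) and among controls between experiments (21 and 124, with experiment labels shuffled), each reached by 2 of 21, for the joint test (114 and 134), reached by 3, from 2.5 to 5 ng/L (3 and 26), reached by 6, and from 5 to 10 ng/L (1 and 797), reached by 7. For these counts chance cannot be excluded. The shuffles weigh only the number of calls and do not judge single transcripts. The counts of 0 at 0.12 ng/L and for the interaction were reached by all 21, as a count of 0 must be, with highest others of 106 and 4. Without replicate 7, no shuffled split reached the counts at 1.2 ng/L (4 and 3), 5 ng/L (6 and 2) and 10 ng/L (77 and 19), with the same limit on the share. There chance cannot be excluded at 2.5 ng/L (5 and 4880), from 1.2 to 2.5 ng/L (4 and 3218), 2.5 to 5 ng/L (3 and 163), 5 to 10 ng/L (1 and 12) and in the joint test (37 and 63), each reached by 3, and from 0.12 to 1.2 ng/L (5 and 13), reached by 2. The count at 0.12 ng/L (0 and 31) was again reached by all 21, as a count of 0 must be. Splits with up to 4880 calls point to a structure among the libraries. Single libraries carry part of it: in place of 4880, 1164 were called without replicate 53 of the 1.2 ng/L group and 2888 and 3114 without replicates 57 and 52 of the 2.5 ng/L group, and without any other library of that shuffled group at least 3681; the cause was not tested. A count alone does not weigh the size of a change. At 1.2 ng/L, 28 of 30 larvae lay above the highest control for FMt030408, 27 for FMt030407, 26 for FMt030406 and 11 for FMt019919. At 10 ng/L all 28 larvae lay above all 29 controls for each of the 4 transcripts.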
